A study of Homo sapiens with 100 samples.

How the data were processed

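Poly(A) RNA was measured by bulk RNA sequencing of transcript 3' ends in 100 cultures of TMD8, an established cell line from a diffuse large B cell lymphoma of the activated B cell type. The cultures came from 11 single-cell clones: 5 wild-type clones and 6 clones that carry the BTK A428D change at the endogenous BTK locus. Each clone was exposed for 24 h to 8 conditions, which gave 88 libraries in 16 groups. A further 12 untreated libraries came from the 11 clones and from the parental line. The treatments, per the labels, were the solvent DMSO, zelebrudomide, bexobrutideg, pomalidomide, venetoclax, and venetoclax combined with each of the other compounds. Doses were not given in the sources used here. The sample titles attach A428D to another gene, SF3B1, whereas the growth and design texts place it in BTK. The clones are called A428D here on the strength of those texts, and 3' end counts cannot check the base change. Group and clone number were taken from the labels.

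Cells were pelleted and lysed in a preservative, and libraries were made by a sequencing company through reverse transcription, second-strand synthesis, tagmentation, indexing and amplification, per the labels' protocols. The submitters' processing notes name FastQC 0.12.1, fastp 0.24.0, STAR 2.7.11, SAMtools 1.22.1, MultiQC 1.32, featureCounts, Subread 2.1.1 and edgeR, and the builds GRCh38 and hg38, with no role or order. The annotation release, the strand setting and any removal of duplicate reads were not given in the sources used here. The deposited table holds estimated counts per gene, not normalised, for 78894 gene identifiers in 100 columns, each matched by name to 1 sample. Of the values, 8.75% were not whole, in fractional steps of the kind left when reads are divided between features. All values were rounded to whole numbers before testing, which changed the summed total by -0.0068%. The 92 synthetic spike-in entries, at most 0.001% of a library, were left out of library sizes and tests. For 36134 identifiers the table gave no symbol, and those were tested but are not named. Positions come from GENCODE release 29 on GRCh38, which held 57342 of the identifiers. Because the strand setting was not stated, overlapping and antisense gene pairs cannot be told apart, and genes with near-identical copies, such as IGLC7, CCL4 and CCL4L2, HSPA1A, MIR3648-1 and MIR3648-2, FABP5P1 and EIF4A1P10, have uncertain counts. ARHGEF10, KBTBD11 and KBTBD11-OT1 lie close together and were read with the same caution.

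Counted reads per library, in units of 1000000, ran from 1.48 to 12.5 with a median of 7.14. The 24 h and untreated libraries differed in depth and were deposited as separate sets, so that the set and the exposure cannot be told apart in any comparison of untreated with DMSO libraries. Within the 24 h set the wild-type groups given venetoclax with zelebrudomide (3.15 to 6.12) or with bexobrutideg (1.48 to 6.11) were the shallowest. Mitochondrial transcripts took 6.24% to 11.1% of counts. Counting precision covers sampling of reads only. In no group did any pair of libraries agree within sampling noise: the lowest chi-square per degree of freedom between a pair was 1.68.

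Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with TMM scaling, its default expression filter (a minimum count of 10 and a minimum total of 15), robust dispersion estimates and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Every adjusted p for a gene in the text is from this test unless another is named, and changes are log2 fold changes with their standard errors (SE). Levels are counts per 1000000 (CPM), given as mean ± SD over clones. They are scaled within the libraries of a fit, so that the same untreated libraries carry other CPM values beside DMSO libraries than alone. Values of single libraries in the closing parts, and means over the 12 untreated libraries, are on library totals without that scaling. The 22 comparisons of treatments within the 24 h set drew on all 88 libraries and 16 groups, with 14962 genes tested. The comparisons of A428D with wild-type clones used only the 11 libraries concerned, with 13397 genes for DMSO and 14564 for untreated cultures, so that each clone entered once. Untreated and DMSO libraries were compared in a fit of 22 libraries and 15354 genes. A difference in response was tested as an interaction, the change in A428D clones minus the change in wild-type clones.

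The replicates are clones, and the same clones were given every condition. Over the 500 most variable genes, deviations from the group mean had a median correlation of 0.63 between 24 h libraries of the same clone (0.66 to 0.87 per A428D clone, but 0.3 to 0.46 per wild-type clone, where the lowest pair was at -0.09) and -0.16 between other clones of the same genotype, and 88 of 88 libraries lay nearest to their own clone. The clone therefore pairs the 24 h libraries. The fit without a clone term was set as the main one before the data were examined, and the fit with the clone as a block is given beside a result where it moves a count by more than 1.5 times or changes a call. Clone numbers of wild-type and A428D clones name unrelated clones.

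Genes named in the text follow a rule set before the data were examined. BTK, IKZF1, IKZF3, CRBN, IRF4, MYC, BCL2 and MCL1 were named whatever their values. Per comparison, up to 10 genes per direction with the largest changes were eligible (5 for combinations and for pairs of compounds), provided that one group averaged at least 10 CPM and that every clone moved the same way or, between genotypes, that the groups did not overlap. Up to 4 members with the smallest adjusted p were eligible from each gene list that passed its test. In the same way, 21 gene lists were fixed from textbook knowledge of signalling, metabolism and cell types. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. List members are counted as risen or fallen from the test over all genes, and the count adjusted over the list alone is given beside it.

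The procedure was tested on simulated counts drawn from the real means, spreads and library sizes with 200 changed genes. For A428D against wild-type clones in DMSO (13397 genes) it recovered 50% of 1.5-fold and 82% of 2-fold changes with 5% false calls, and DESeq2 56% and 82% with 11%. For zelebrudomide in wild-type clones (14962 genes, as below) it recovered 43% and 71% with 0% false calls. The clone block gave 59% and 80% with 3.5%. The zelebrudomide response difference gave 27% and 62%. Bexobrutideg in A428D clones gave 53% and 82% with 0.7%, and the clone block 71% and 92% with 8.9%. A planted list gave a camera p of 2.15e-70, and 0 of 100 random lists an unadjusted p under 0.05. Random lists lack the correlation within real ones, so false passes of those were not tested.

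The alternatives set before the data were examined were DESeq2 1.42.0 with its own size factors, edgeR with RLE scaling, no expression filter, only the groups compared in the fit, the clone block, leaving out each clone with all its libraries, and the estimated correlation in camera. Leaving out the shallowest library, wild-type clone 3 given bexobrutideg with venetoclax, was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.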

Results

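Transcript levels were measured by 3' end RNA sequencing in TMD8, an established line of activated B cell type diffuse large B cell lymphoma, whose growth depends on B cell receptor signalling through the kinase BTK. The series asks how a BTK change, A428D, alters the response to BTK degraders. In the 24 h set, 5 wild-type and 6 A428D clones each received 8 conditions, which gave 16 groups of 5 or 6 libraries. Zelebrudomide is a BTK degrader that also directs cereblon, an E3 ligase subunit, against the B cell transcription factors IKZF1 and IKZF3. Bexobrutideg is a BTK degrader without that activity, pomalidomide is a cereblon-binding degrader of IKZF1 and IKZF3 that does not act on BTK, and venetoclax inhibits the survival protein BCL2. Doses were not given in the sources used here. Untreated cultures of the 11 clones and of the parental line made a further 12 libraries. Depth is given in counted reads per library, in units of 1000000. Wild-type libraries held 6.86 to 9.39 under DMSO, 6.01 to 7.82 with zelebrudomide, 6.24 to 7.16 with bexobrutideg, 6.44 to 7.96 with pomalidomide and 6.49 to 7.39 with venetoclax. A428D libraries held 6.85 to 8.08, 7 to 8.66, 5.15 to 8.87, 6.75 to 8.33 and 5.81 to 7.92 in the same order. With venetoclax added, wild-type libraries held 3.15 to 6.12 (zelebrudomide), 1.48 to 6.11 (bexobrutideg) and 5.81 to 6.9 (pomalidomide), and A428D libraries 6.27 to 7.31, 5.05 to 7.61 and 5.87 to 8.25. Untreated libraries were deeper, at a mean of 11.72 ± 0.68 (SD) in 5 wild-type clones, 11.18 ± 0.47 in 6 A428D clones and 10.88 in the parental line.

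The genes at the centre of the series were BTK (ENSG00000010671, GRCh38 chromosome X, 101349447 to 101390796), IKZF1 (ENSG00000185811, chromosome 7, 50304068 to 50405101) and IKZF3 (ENSG00000161405, chromosome 17, 39757715 to 39864188). Cereblon is encoded by CRBN (ENSG00000113851, chromosome 3, 3144628 to 3179727). Their outputs and survival genes were IRF4 (ENSG00000137265, chromosome 6, 391739 to 411447), MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), BCL2 (ENSG00000171791, chromosome 18, 63123346 to 63320128) and MCL1 (ENSG00000143384, chromosome 1, 150574551 to 150579738). Where one of these 8 genes is not given for a comparison, it did not pass the test there. Changes below are log2 fold changes ± SE, and levels are mean CPM ± SD over 5 wild-type or 6 A428D clones. Genes named for the size of a treatment effect moved the same way in 5 of 5 or 6 of 6 clones, and genes named for the size of a genotype difference did not overlap between the groups.

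Under DMSO, genes that differed between A428D and wild-type clones included members of the integrated stress response, plasma cell and B cell identity lists, each with adjusted p = 0.244 with an estimated correlation. SPIC, a transcription factor of the PU.1 family, was higher by 3.77 ± 0.63 (adjusted p = 0.00782), from 0.873 ± 0.409 CPM in wild-type clones. The class II gene HLA-DQB1 was higher by 1.53 ± 0.29 and the surface receptors CD84 and CD83 by 1.24 ± 0.17 and 1.03 ± 0.11. BTK itself stood at 64.2 ± 4.31 CPM in A428D and 68 ± 3.12 in wild-type clones (-0.08 ± 0.07, adjusted p = 0.483), and IRF4, MYC, BCL2, MCL1, IKZF1, IKZF3 and CRBN did not pass the test either.

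Of 26 integrated stress response genes, 11 were lower in A428D clones and none higher (14 adjusted over the list alone), among them SESN2 (-1.52 ± 0.21), CHAC1 (-1.79 ± 0.31) and the serine synthesis enzyme PHGDH (-1.28 ± 0.27). Of 19 plasma cell genes 7 were lower (14 adjusted over the list alone), with the endoplasmic reticulum proteins HSP90B1 at -0.83 ± 0.12 and PDIA4 at -0.69 ± 0.13. Of 26 B cell and germinal centre identity genes 6 were higher (9 higher and 1 lower adjusted over the list alone), including HLA-DRB1 (0.95 ± 0.14) and CD72 (0.44 ± 0.07). Camera gave adjusted p = 1.69e-09, 3.81e-07 and 0.00141 for these lists, and adjusted p = 0.244 with an estimated correlation for each. Hypoxia and glycolysis genes (2 of 24 higher, 7 higher and 1 lower adjusted over the list alone) also passed, as did proliferation genes (0 of 26 by both counts) and cholesterol synthesis genes (0 of 18 by both counts). They gave adjusted p = 0.766, 0.85 and 0.797 with an estimated correlation, and the cholesterol list adjusted p = 0.227 with the clone block. In total 955 of 13397 genes were called, 442 higher and 513 lower, of which 133 changed at least 2-fold, and 1538 with no expression filter. The count rose to 2097 without A428D clone 1 and fell to 554, 617 and 457 without clones 4 to 6. It fell to 443, 476, 437 and 488 without wild-type clones 1 to 4.

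In untreated cultures, A428D clones carried higher immediate early transcripts. FOS, an AP-1 transcription factor induced by ERK signalling, averaged 557 ± 115 CPM against 171 ± 17.4 in wild-type clones (1.70 ± 0.15, adjusted p = 0.000189). FOSB was higher too (2.12 ± 0.26), and the activation marker CD69 was higher by 2.37 ± 0.36. Of 22 ERK and immediate early genes 14 were higher and none lower (16 and 1 adjusted over the list alone), with EGR1 at 1.00 ± 0.05, EGR2 at 0.93 ± 0.06 and DUSP2 at 0.71 ± 0.06. The list passed with adjusted p = 9.35e-15 and with adjusted p = 0.00297 with an estimated correlation. Of 33 interferon-stimulated genes 17 were higher (26 adjusted over the list alone), such as ISG20 (0.65 ± 0.10) and IFIT1 (1.39 ± 0.21). Camera gave adjusted p = 9.33e-16, and adjusted p = 0.17 with an estimated correlation.

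B cell and germinal centre identity genes were higher for 8 of 26 (11 adjusted over the list alone), with CD72 at 0.80 ± 0.09 and CIITA, the regulator of class II genes, at 0.45 ± 0.08. Among BCR and TLR signalling components 5 of 24 were higher (6 adjusted over the list alone), with TLR9 at 0.33 ± 0.07. Camera gave adjusted p = 9.15e-05 and 0.0201, and adjusted p = 0.292 and 0.281 with an estimated correlation. Of 25 MYC and ribosome biogenesis targets 6 were lower by small amounts (14 adjusted over the list alone), such as HSPD1 at -0.17 ± 0.04, with adjusted p = 4.15e-08, and adjusted p = 0.0252 with an estimated correlation. The survival gene MCL1 was higher by 0.36 ± 0.06 (adjusted p = 0.00206), whereas BTK (0.03 ± 0.06) and IRF4 (-0.24 ± 0.11) did not pass. ARHGEF10, KBTBD11 and KBTBD11-OT1, which lie close together, were each lower by nearly 1 log2 unit (ARHGEF10 by -0.98 ± 0.15). SPIC was higher by 3.66 ± 0.73 (adjusted p = 0.0223), a call that ended without any of wild-type clones 2 to 5 (adjusted p = 0.0582, 0.0607, 0.0596 and 0.0651). In all, 859 of 14564 genes were called, 510 higher and 349 lower, and 1294 with no expression filter. The count was 530 without A428D clone 3 and 552 without clone 5, and 490, 518, 412 and 440 without wild-type clones 2 to 5.

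**Figure D1:**
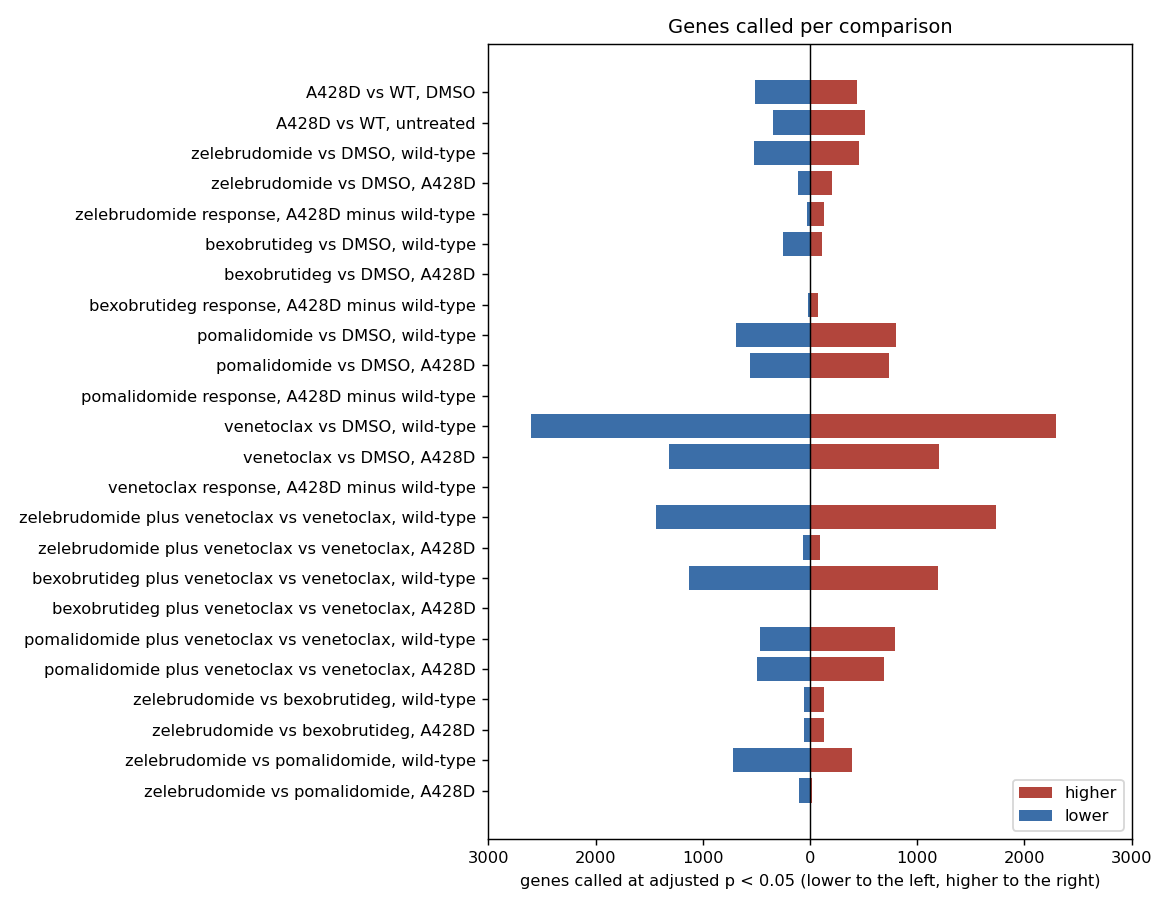
Genes called at an adjusted p under 0.05 in 24 comparisons, as bars to the right of 0 for higher and to the left for lower. Bexobrutideg called 366 genes in wild-type clones and 0 in A428D clones, whereas pomalidomide called 1495 and 1298.

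Zelebrudomide in wild-type clones lowered the transcriptional output of B cell receptor and NF-kB signalling, lowered amino acid stress genes, and raised interferon-stimulated genes. IRF4, a lymphoma survival factor downstream of BTK, fell from 445 ± 29.7 to 195 ± 10.7 CPM (-1.19 ± 0.15, adjusted p = 1.11e-08). MYC fell from 116 ± 18.5 to 67.1 ± 11.6 (-0.78 ± 0.20, adjusted p = 0.00572). The feedback inhibitor NFKBIA changed by -1.07 ± 0.10, RELB by -1.11 ± 0.12 and the ERK targets EGR2 and DUSP2 by -2.34 ± 0.42 and -1.21 ± 0.19. IKZF1 transcript rose from 198 ± 7.69 to 299 ± 13.9 CPM (0.59 ± 0.07, adjusted p = 8.86e-10), while BTK transcript did not pass (0.18 ± 0.10, adjusted p = 0.334, and 0.0706 with the clone block). IKZF3 gave -0.17 ± 0.09 (adjusted p = 0.305, and 0.0446 with the clone block).

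Of 30 BCR NF-kB targets, 16 fell and 2 rose with zelebrudomide in wild-type clones (19 and 2 adjusted over the list alone), and 6 of 20 ERK and immediate early genes fell (6 adjusted over the list alone). Of 26 integrated stress response genes 18 fell (19 adjusted over the list alone), with CEBPG at -0.81 ± 0.12, the serine synthesis enzyme PSAT1 at -1.48 ± 0.20 and the amino acid transporter SLC7A5 at -0.72 ± 0.11. Interferon-stimulated genes rose for 7 of 34 (15 adjusted over the list alone), such as PARP9 (0.77 ± 0.12), XAF1 (1.34 ± 0.26) and IFIT3 (1.77 ± 0.40). These lists passed both ways, with adjusted p = 4.88e-16, 0.000398, 1.82e-22 and 2.25e-10, and with adjusted p = 2.81e-05, 0.00556, 0.000117 and 0.0447 with an estimated correlation. Proliferation genes (1 of 26 fell by both counts) and MYC and ribosome biogenesis targets (2 of 25 fell by both counts) passed with adjusted p = 0.609 and 0.454 with an estimated correlation. Mitochondrially encoded transcripts, kept as a sign of RNA quality, were higher as a list (0 of 13 called by both counts, adjusted p = 0.0204, and adjusted p = 0.526 with an estimated correlation). The fibroblast and endothelial list rested on PECAM1 among 3 measured members (1.87 ± 0.37, 1 rose by both counts, adjusted p = 0.022, and adjusted p = 0.0447 with an estimated correlation).

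Increases with zelebrudomide in wild-type clones included LDB3 (2.41 ± 0.22), the immune checkpoint gene VSIR (2.40 ± 0.33), the light chain segment IGLC7 (1.92 ± 0.36), VPREB3 (1.72 ± 0.26) and DAPK2 (1.68 ± 0.14). Decreases included LBH (-1.53 ± 0.13) and CEBPB (-1.24 ± 0.16). BCL2 fell (-0.51 ± 0.13, adjusted p = 0.00737, and 0.0594 without wild-type clone 3), whereas MCL1 (-0.02 ± 0.09) did not pass. In all 983 of 14962 genes were called, 457 higher and 526 lower, and 2421 with the clone block and 2085 with only the groups compared. The count was 610, 550, 636 and 598 without wild-type clones 1, 2, 4 and 5.

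In A428D clones, zelebrudomide raised IKZF1 transcript from 176 ± 9.35 to 288 ± 24.3 CPM (0.71 ± 0.06, adjusted p = 2.23e-14). IRF4 (0.07 ± 0.14, adjusted p = 0.974) and MYC (0.07 ± 0.18, adjusted p = 0.984) did not pass. LDB3 (1.66 ± 0.20), RASSF4 (1.52 ± 0.17), DEPP1 (1.20 ± 0.15) and the purine enzyme ADA (1.14 ± 0.13) rose. LRRN3 (-1.95 ± 0.22), CRYM (-1.35 ± 0.21), the B cell transcription factor IRF8 (-0.91 ± 0.11) and LBH (-0.75 ± 0.11) fell. BCR NF-kB targets rose for 2 of 30 and none fell (5 adjusted over the list alone), among them CCND2 (0.89 ± 0.12). Interferon-stimulated genes rose for 4 of 34 (7 rose and 1 fell adjusted over the list alone), such as OAS3 (0.89 ± 0.19) and PARP9 (0.52 ± 0.11). These and the integrated stress response (1 of 26 rose by both counts), cholesterol synthesis (0 of 18 by both counts) and cereblon substrate lists (1 of 14 rose by both counts, IKZF1) passed camera. They gave adjusted p = 0.137, 0.266, 0.622, 0.753 and 0.137 with an estimated correlation. There were 308 genes called, 201 higher and 107 lower, 1007 with the clone block and 121 with only the groups compared. Without A428D clones 2, 4, 5 and 6 the count was 187, 175, 194 and 201.

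The genes whose zelebrudomide response differed between genotypes included BCR NF-kB and integrated stress response genes. The change in A428D clones exceeded that in wild-type clones by 1.26 ± 0.20 for IRF4 (adjusted p = 4.18e-05), 1.16 ± 0.14 for NFKBIA, 1.11 ± 0.16 for RELB. It did so by 2.57 ± 0.47 for the cytokine IL10 and 1.55 ± 0.26 for PSAT1. MYC differed by 0.86 ± 0.27 (adjusted p = 0.0997, and 0.000537 with the clone block), BCL2 by 0.61 ± 0.18 (adjusted p = 0.0678, and 0.000109 with the clone block), MYC and BCL2 passing without the shallowest library too, and IKZF1 by 0.12 ± 0.09 (adjusted p = 0.733). Of 30 BCR NF-kB targets 11 had a higher change in A428D clones (15 adjusted over the list alone). So had 13 of 26 integrated stress response genes (21 adjusted over the list alone), including ATF4 (1.14 ± 0.21) and CEBPB (1.08 ± 0.22). ERK and immediate early genes did so for 2 of 20 (5 adjusted over the list alone), and STAT3 and cytokine targets for 2 of 14 (3 adjusted over the list alone), including BATF (0.98 ± 0.19). The lists passed with adjusted p = 2.2e-26, 1.24e-31, 6.6e-05 and 0.00649, and with adjusted p = 5.04e-08, 3.57e-06, 0.00139 and 0.0242 with an estimated correlation. Proliferation, MYC and ribosome biogenesis, cholesterol synthesis, and hypoxia and glycolysis genes passed toward a higher change in A428D clones, and interferon-stimulated, mitochondrially encoded, and fibroblast and endothelial genes toward a lower one, with 0 members called over all genes. With an estimated correlation the adjusted p was 0.557 for proliferation genes, 0.077 for fibroblast and endothelial genes and 0.428 for each of the others. VPREB3 (-1.61 ± 0.36) and the metallothionein MT1X (-0.79 ± 0.18) showed the opposite difference. In total 155 genes differed, 127 with a higher and 28 with a lower change in A428D clones, and 1011 with the clone block, 345 with no expression filter and 276 without the shallowest library. The count was 237 and 94 without A428D clones 1 and 5, and 82 and 91 without wild-type clones 2 and 5.

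**Figure D2:**
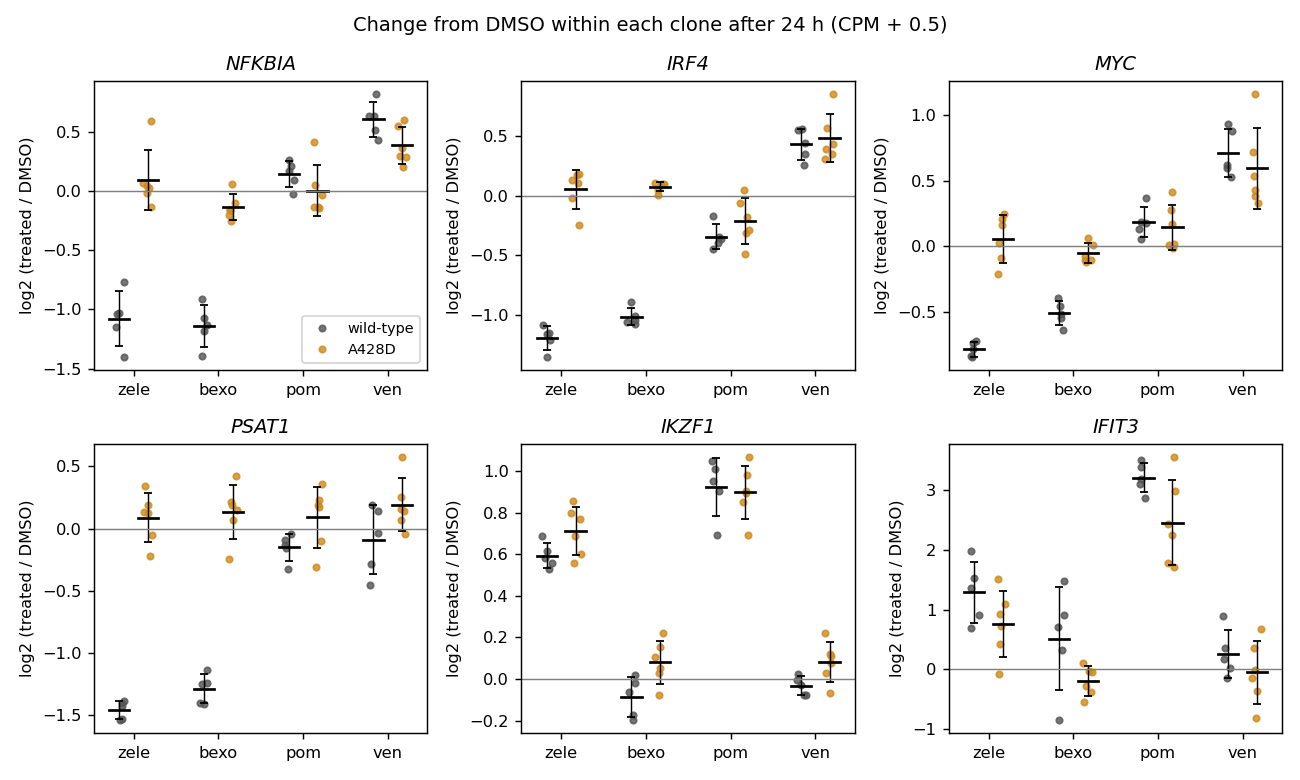
Log2 change from DMSO of 6 genes in each clone after 24 h with zelebrudomide (zele), bexobrutideg (bexo), pomalidomide (pom) or venetoclax (ven), points being clones and black bars the mean ± SD of 5 wild-type or 6 A428D clones. NFKBIA and IRF4 fell in every wild-type clone given either BTK degrader, and IKZF1 rose in every clone of both genotypes given zelebrudomide or pomalidomide.

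Bexobrutideg in wild-type clones lowered BCR NF-kB and integrated stress response genes. IRF4 fell from 445 ± 29.7 to 220 ± 8.99 CPM (-1.02 ± 0.15, adjusted p = 2.45e-06). NFKBIA fell by a log2 change of -1.14 ± 0.10, RELB by -1.19 ± 0.12, the NF-kB regulator NFKBID by -1.65 ± 0.17 and the cytokine IL10 by -1.97 ± 0.40. The precursor of miR-155, MIR155HG, changed by -1.48 ± 0.17, EGR2 by -2.16 ± 0.41 and PSAT1 by -1.30 ± 0.19. IKZF1 stood at 186 ± 7.74 CPM against 198 ± 7.69 under DMSO (-0.09 ± 0.07, adjusted p = 0.631). MYC stood at 81.9 ± 17.1 against 116 ± 18.5 (-0.50 ± 0.20, adjusted p = 0.202, and 0.00448 with the clone block). BCL2 gave -0.33 ± 0.13 (adjusted p = 0.204, and 0.0039 with the clone block).

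With bexobrutideg in wild-type clones, 15 of 30 BCR NF-kB targets fell and none rose (21 fell adjusted over the list alone). Integrated stress response genes fell for 18 of 26 (23 adjusted over the list alone), with ATF4 at -0.97 ± 0.15. ERK and immediate early genes fell for 3 of 20 (8 adjusted over the list alone), and STAT3 and cytokine targets for 3 of 14 (4 fell and 1 rose adjusted over the list alone), with BATF at -0.91 ± 0.15. Camera gave adjusted p = 6.14e-32, 2.53e-32, 2.01e-06 and 0.00477, and adjusted p = 2.53e-09, 2.78e-06, 0.000155 and 0.0119 with an estimated correlation. Interferon-stimulated genes were higher as a list though 0 of 34 were called (3 adjusted over the list alone), with adjusted p = 0.168 with an estimated correlation. Proliferation, MYC and ribosome biogenesis, cholesterol synthesis, hypoxia and glycolysis, and mitochondrially encoded genes also passed, with adjusted p = 0.547 with an estimated correlation for each. Increases were fewer, among them the taste receptor subunit TAS1R3 (1.84 ± 0.39), the sulfotransferase CHST2 (1.11 ± 0.20), the lipid antigen presenter CD1D (0.99 ± 0.22) and DAPK2 (0.87 ± 0.14). In all 366 genes were called, 110 higher and 256 lower, 1582 with the clone block, 660 with no expression filter and 1094 with only the groups compared. The count was 222, 161, 200 and 212 without wild-type clones 1, 2, 4 and 5.

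No gene was called for bexobrutideg in A428D clones by edgeR (0 of 14962, with 288 at an unadjusted p under 0.05) or by DESeq2 (0), 2 were with the clone block and 4 with no expression filter. IRF4 averaged 393 ± 73 CPM against 373 ± 66.5 under DMSO (0.08 ± 0.14, 95% interval -0.19 to 0.34), and MYC changed by -0.06 ± 0.18 (95% interval -0.41 to 0.29). The integrated stress response, cholesterol synthesis, and hypoxia and glycolysis lists lay above other genes by camera although 0 of their 26, 18 and 24 measured members were called by either count. They gave adjusted p = 0.688, 0.876 and 0.876 with an estimated correlation. The difference from the wild-type response itself was called for 92 genes, 74 of them with a higher change in A428D clones, for 753 with the clone block, 288 with no expression filter and 140 without the shallowest library. BCL2 differed by 0.43 ± 0.18 (adjusted p = 0.444, and 0.0123 with the clone block). IRF4 differed by 1.09 ± 0.20 (adjusted p = 0.000681), NFKBIA by 1.00 ± 0.14 and NFKBID by 1.58 ± 0.22. ATF4 differed by 1.12 ± 0.21, SESN2 by 1.92 ± 0.37 and SLC7A1 by 1.44 ± 0.24. SESN2 was already lower in A428D clones under DMSO, and its difference includes that gap. Differences were called for 9 of 30 BCR NF-kB targets, 11 of 26 integrated stress response and 2 of 20 ERK and immediate early genes. Adjusted over the list alone they numbered 13, 22 and 3. These lists gave adjusted p = 6.62e-07, 6.62e-07 and 0.00773 with an estimated correlation. Proliferation, cholesterol synthesis, and hypoxia and glycolysis genes passed toward a higher change in A428D clones, and interferon-stimulated and mitochondrially encoded genes toward a lower one, with 0 members called. With an estimated correlation these gave adjusted p = 0.608, 0.464, 0.464, 0.3 and 0.573. Without wild-type clone 2 the count was 48.

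Pomalidomide raised interferon-stimulated genes and IKZF1 transcript in both genotypes and left BTK transcript unmoved by the test. IKZF1 rose from 198 ± 7.69 to 376 ± 28.4 CPM in wild-type clones (0.93 ± 0.07) and from 176 ± 9.35 to 329 ± 32.7 in A428D clones (0.90 ± 0.06). The antiviral gene IFIT3 rose by 3.88 ± 0.33 and 2.82 ± 0.26, the secreted glycoprotein gene LGALS3BP by 3.44 ± 0.33 and 3.62 ± 0.30. IGLC7 rose by 3.17 ± 0.37 and 3.13 ± 0.35, and RASSF4 by 2.87 ± 0.19 and 2.54 ± 0.17. IRF8 fell by a log2 change of -2.13 ± 0.13 and -1.83 ± 0.12, LRRN3 by -2.39 ± 0.29 and -2.51 ± 0.24, and the BH3-only gene HRK by -1.92 ± 0.31 and -1.33 ± 0.28. BTK (0.04 ± 0.10 and 0.14 ± 0.09), MYC (0.18 ± 0.19 and 0.14 ± 0.18) and IRF4 (-0.34 ± 0.15 and -0.20 ± 0.14) did not pass. IRF4 did in wild-type clones with the clone block (adjusted p = 0.00346).

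Of 34 interferon-stimulated genes, 24 rose and 1 fell with pomalidomide in each genotype (26 and 1 in wild-type and 27 and 1 in A428D clones adjusted over the list alone). OAS3 stood at 1.84 ± 0.20 and 1.93 ± 0.18. BCR NF-kB targets held 13 risen and 1 fallen of 30 in wild-type clones (16 and 3 adjusted over the list alone). In A428D clones 7 rose and 2 fell (7 and 2 adjusted over the list alone), CCND2 giving 1.02 ± 0.13 and 1.04 ± 0.12. Of 14 STAT3 and cytokine targets 6 and 3 rose (6 rose and 1 fell, and 5 rose, adjusted over the list alone), including SOCS3 at 0.78 ± 0.12 and 0.68 ± 0.11. With an estimated correlation, wild-type clones gave adjusted p = 0.000928, 0.00503 and 0.000928 for these lists, and A428D clones gave adjusted p = 0.000151, 0.27 and 0.01. In wild-type clones 5 of 17 PI3K-FOXO genes fell by both counts, among them the migration regulator KLF2 (-1.16 ± 0.18), with adjusted p = 0.122 with an estimated correlation. MYC and ribosome biogenesis and cholesterol synthesis genes passed there too, both with adjusted p = 0.538 with an estimated correlation. In A428D clones the integrated stress response (3 of 26 rose), cholesterol synthesis (2 of 18 rose) and cereblon substrate lists (2 of 14 rose) passed with adjusted p = 0.471, 0.471 and 0.0835 with an estimated correlation. The cereblon list gave adjusted p = 0.0821 with the clone block.

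Pomalidomide called 1495 genes in wild-type clones (802 higher, 693 lower) and 1298 in A428D clones (736 higher, 562 lower), or 2879 and 2493 with the clone block and 2507 and 845 with only the groups compared. The difference between genotypes was called for 0 genes by edgeR (253 at an unadjusted p under 0.05) and 0 by DESeq2, for 7 with the clone block and 2 with no expression filter. The IKZF1 response differed by -0.02 ± 0.09 (95% interval -0.20 to 0.16). BCR NF-kB targets responded less in A428D clones as a list (adjusted p = 3.16e-05, and adjusted p = 0.0722 with an estimated correlation) with 0 of 30 members called by both counts.

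**Figure D3:**
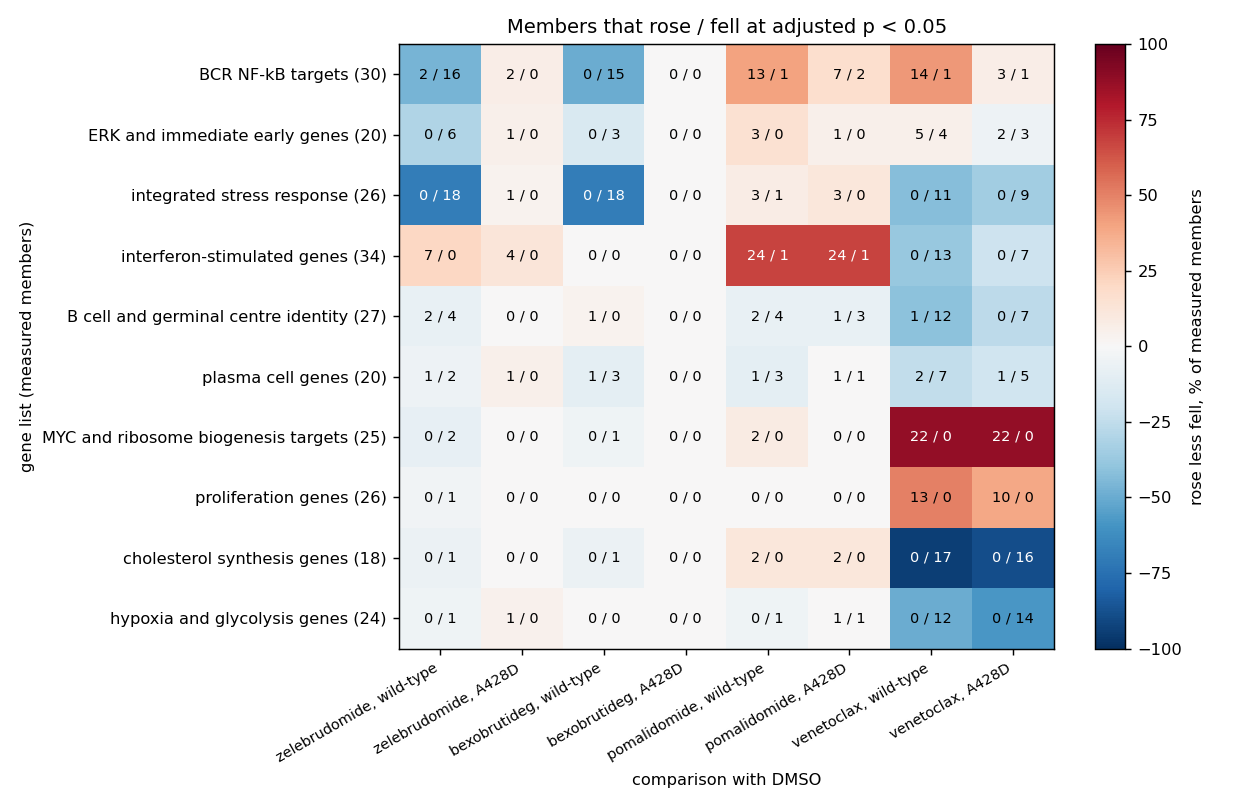
Members of 10 gene lists that rose / fell at an adjusted p under 0.05 against DMSO, for 4 compounds in wild-type and A428D clones, with colour giving rose less fell as a percentage of measured members. The fall of 15 BCR NF-kB targets and 18 integrated stress response genes with bexobrutideg in wild-type clones stands against 0 in A428D clones, and 24 interferon-stimulated genes rose with pomalidomide in each genotype.

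Venetoclax changed more genes than any other single compound in both genotypes (4903 and 2519). MCM4, a subunit of the replicative helicase, rose from 22.8 ± 5.63 to 76.9 ± 13.3 CPM in wild-type clones (1.75 ± 0.28) and from 30.9 ± 11.5 to 66.2 ± 12.8 in A428D clones (1.10 ± 0.26). The nucleotide enzyme RRM2 rose by 1.69 ± 0.27 and 1.18 ± 0.25. BBC3, which encodes the BCL2 antagonist PUMA, fell by a log2 change of -1.21 ± 0.10 and -0.98 ± 0.09, and BMF by -1.18 ± 0.16 and -0.84 ± 0.15. BID rose by 0.99 ± 0.13 and 0.48 ± 0.12. MYC rose by 0.70 ± 0.19 in wild-type and 0.57 ± 0.18 in A428D clones (adjusted p = 0.00347 and 0.0185, the second 0.0884 without A428D clone 3). IRF4 rose by 0.43 ± 0.15 and 0.48 ± 0.14 (adjusted p = 0.019 and 0.00878, the first 0.0524 without wild-type clone 5). MCL1 fell in wild-type clones (-0.47 ± 0.09) and gave -0.21 ± 0.08 in A428D clones (adjusted p = 0.0514, 0.0035 with the clone block and 0.0195 without the shallowest library), and the response difference of 0.26 ± 0.12 did not pass. The target gene BCL2 did not pass (-0.31 ± 0.13 and -0.28 ± 0.12, with adjusted p = 0.00211 and 0.00564 with the clone block). IKZF3 fell in wild-type clones (-0.31 ± 0.09, adjusted p = 0.00401, and 0.141 with no expression filter).

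Of 25 MYC and ribosome biogenesis targets 22 rose in each genotype with venetoclax (22 in each adjusted over the list alone), such as NOLC1 at 1.04 ± 0.11 and 0.72 ± 0.11. The list passed with adjusted p = 0.00705 in wild-type and 0.007 in A428D clones with an estimated correlation. PI3K-FOXO genes did so as well (10 of 17 fell and 1 rose in wild-type clones, 13 and 1 adjusted over the list alone, and 7 fell in A428D clones, 10 adjusted over the list alone). They gave adjusted p = 0.00705 and 0.007 with an estimated correlation, with FBXO32 at -1.48 ± 0.24 and -0.87 ± 0.20. Of 18 cholesterol synthesis genes 17 fell in wild-type and 16 in A428D clones by both counts, such as HMGCS1 at -1.31 ± 0.18 and -0.73 ± 0.16. Of 24 hypoxia and glycolysis genes 12 and 14 fell (14 and 18 adjusted over the list alone), such as ALDOC at -1.48 ± 0.20 and -1.27 ± 0.18. Proliferation genes rose for 13 and 10 of 26 (13 and 11 adjusted over the list alone). With an estimated correlation these lists gave adjusted p = 0.06, 0.17 and 0.28 in wild-type and adjusted p = 0.0877, 0.0588 and 0.358 in A428D clones.

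The BCL2 family list held 2 risen and 5 fallen members of 14 with venetoclax in wild-type clones (2 and 6 adjusted over the list alone). It held 1 and 5 in A428D clones (1 and 7 adjusted over the list alone). In wild-type clones p53 targets held 1 risen and 10 fallen of 25 (1 and 11 adjusted over the list alone). In A428D clones they held 1 and 7 (1 and 8 adjusted over the list alone), such as CCNG1 at -0.93 ± 0.15 and -0.76 ± 0.13. Integrated stress response genes fell for 11 and 9 of 26 (14 and 12 adjusted over the list alone), with DDIT3 at -0.99 ± 0.20 and -1.41 ± 0.20. Estimated correlations gave adjusted p = 0.17, 0.107 and 0.226 for these in wild-type and adjusted p = 0.0562, 0.0687 and 0.0877 in A428D clones. Interferon-stimulated genes fell for 13 and 7 of 34 by both counts, with OAS1 at -0.87 ± 0.13 and -0.73 ± 0.12. B cell identity genes fell for 12 and 7 of 27 (12 and 9 adjusted over the list alone), with HLA-DMA at -0.79 ± 0.15 and -0.63 ± 0.14. BCR NF-kB targets rose for 14 and 3 of 30 (15 and 3 adjusted over the list alone), with NFKBIA at 0.61 ± 0.10 and 0.38 ± 0.09. For these, estimated correlations gave adjusted p = 0.28, 0.272 and 0.0505 in wild-type and adjusted p = 0.372, 0.29 and 0.29 in A428D clones. In wild-type clones plasma cell genes (7 of 20 fell) and BCR and TLR components (11 of 24 fell) passed with adjusted p = 0.28 and 0.263 with an estimated correlation.

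Venetoclax called 4903 genes in wild-type clones (2299 higher, 2604 lower) and 2519 in A428D clones (1204 higher, 1315 lower, and 4595 with the clone block), and 1418 in the latter without A428D clone 3. The difference between genotypes was called for 0 genes by edgeR (709 at an unadjusted p under 0.05) and 0 by DESeq2, for 26 with the clone block and 4 with no expression filter. As lists, cholesterol synthesis genes responded less negatively in A428D clones (median difference 0.34, 1 of 18 called adjusted over the list alone). MYC and ribosome biogenesis targets responded less positively (median -0.22). Each gave adjusted p = 0.224 with an estimated correlation. Interferon-stimulated and proliferation genes also passed, with 0 of 34 and 0 of 26 called by both counts and adjusted p = 0.488 and 0.625 with an estimated correlation. BCR NF-kB targets did so too (median -0.23, 0 of 30 called, adjusted p = 0.0491 with an estimated correlation).

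Adding zelebrudomide to venetoclax lowered BCR NF-kB and MYC-linked genes in wild-type clones. The difference between genotypes was not tested for combinations or for pairs of compounds. IRF4 stood at 223 ± 16.3 CPM against 600 ± 25.9 with venetoclax alone (-1.43 ± 0.15), and MYC at 109 ± 9.61 against 188 ± 12.1 (-0.78 ± 0.20). NFKBIA changed by -1.40 ± 0.11, EBI3 by -2.04 ± 0.19 and ATF4 by -1.28 ± 0.16, and VSIR rose by 3.01 ± 0.38. Among 30 BCR NF-kB targets 21 fell and 1 rose (22 and 1 adjusted over the list alone), and of 26 integrated stress response genes 17 fell (21 adjusted over the list alone). Of 25 MYC and ribosome biogenesis targets 17 fell (23 adjusted over the list alone), and of 34 interferon-stimulated genes 18 rose (19 adjusted over the list alone). These gave adjusted p = 2.61e-06, 0.0017, 0.0498 and 0.0439 with an estimated correlation. ERK and immediate early genes fell for 8 of 20 (1 rose) with adjusted p = 0.0128 with an estimated correlation. STAT3 and cytokine targets, proliferation genes and mitochondrially encoded transcripts (4 of 13 rose by both counts) lost their call, with adjusted p = 0.0625, 0.632 and 0.438 with an estimated correlation. The 3 measured fibroblast and endothelial members included PECAM1 at 2.46 ± 0.44 (1 rose, 2 adjusted over the list alone, adjusted p = 0.0498 with an estimated correlation). BTK (0.27 ± 0.10, adjusted p = 0.0419) lost its call without any clone except A428D clone 1 and wild-type clone 3. It gave adjusted p = 0.258 without wild-type clone 1 and 0.0716 to 0.164 without the others, and with no expression filter (0.632). IKZF1 (0.38 ± 0.07, adjusted p = 2.89e-05) and CRBN (0.51 ± 0.13, adjusted p = 0.002) rose and lost their call with no expression filter (0.142 and 0.0834). BCL2 gave -0.35 ± 0.14 (adjusted p = 0.0548, and 0.00152 with the clone block). In A428D clones IKZF1 rose by 0.45 ± 0.06 and RASSF4 by 1.62 ± 0.17, LRRN3 changed by -1.75 ± 0.24 and IRF8 by -0.88 ± 0.12, and IRF4 (-0.16 ± 0.14, adjusted p = 0.893) did not pass. Interferon-stimulated genes were the list that passed there (2 of 34 rose, 7 adjusted over the list alone, adjusted p = 0.308 with an estimated correlation). The counts were 3175 in wild-type clones (1737 higher, 1438 lower, 4863 with the clone block, 2090 without clone 5). They were 160 in A428D clones (98 higher, 62 lower, 764 with the clone block, 245 with no expression filter, 92 with only the groups compared, and 98, 88 and 97 without clones 4, 5 and 6).

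Adding bexobrutideg to venetoclax lowered NF-kB and stress genes in wild-type clones as well. NFKBIA changed by -1.53 ± 0.11, EBI3 by -2.45 ± 0.20, ATF4 by -1.37 ± 0.16 and IRF4 by -0.96 ± 0.15, and the inhibitor of differentiation ID3 rose by 1.94 ± 0.28. BCR NF-kB targets fell for 22 of 30 (24 adjusted over the list alone) and integrated stress response genes for 16 of 26 (19 adjusted over the list alone). Of 20 ERK and immediate early genes 7 fell and 1 rose, and of 14 STAT3 and cytokine targets 6 fell and 3 rose, by both counts. Of 17 PI3K-FOXO genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), including BCL2L11 (0.46 ± 0.09). With an estimated correlation these gave adjusted p = 1.39e-07, 0.00499, 0.0346, 0.0213 and 0.0346. With it, interferon-stimulated genes (9 of 34 rose, 1 fell) and MYC and ribosome biogenesis targets (16 of 25 fell) gave adjusted p = 0.151 and 0.0765. The library of wild-type clone 3 in this group was the shallowest and stood apart from the other 4, with MYC at 378.3 CPM against 103.2 to 141 in the others. Without that library, an alternative chosen after the data had been seen, MYC changed by -0.62 ± 0.17 (adjusted p = 0.00803) in place of -0.13 ± 0.20 (adjusted p = 0.724). IRF4 changed by -1.28 ± 0.14 and MCL1 by 0.24 ± 0.08 in place of 0.42 ± 0.09, a call lost with no expression filter (0.0757) and with only the groups compared (0.159). BTK changed by 0.26 ± 0.08 (adjusted p = 0.0194) in place of 0.15 ± 0.10 (adjusted p = 0.314). CRBN changed by 0.40 ± 0.13 (adjusted p = 0.0297) in place of 0.43 ± 0.13 (adjusted p = 0.0152). Its call ended without wild-type clone 4 (0.0523), without clone 5 (0.0875) and with no expression filter (0.295). BCL2 gave -0.22 ± 0.14 with all libraries (adjusted p = 0.28, and 0.043 with the clone block). Without that library B cell identity genes rose for 11 of 27 and fell for 1, with adjusted p = 0.000177 (0.884 with it), and adjusted p = 0.0437 with an estimated correlation. Mitochondrially encoded transcripts were higher as a list there (1 of 13 rose, adjusted p = 0.00109, and adjusted p = 0.332 with an estimated correlation). The PI3K-FOXO list gave adjusted p = 0.0498, and adjusted p = 0.13 with an estimated correlation. Proliferation genes (0.0465) and BCR and TLR components (0.0498) passed there too, with adjusted p = 0.802 and 0.32 with an estimated correlation. There were 2321 genes called in wild-type clones (1197 higher, 1124 lower, 3798 with the clone block and 571 with only the groups compared). In A428D clones edgeR called 0 genes with or without the clone block (232 at an unadjusted p under 0.05) and DESeq2 called 0, and IRF4 changed by -0.12 ± 0.14 (95% interval -0.38 to 0.15).

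**Figure D4:**
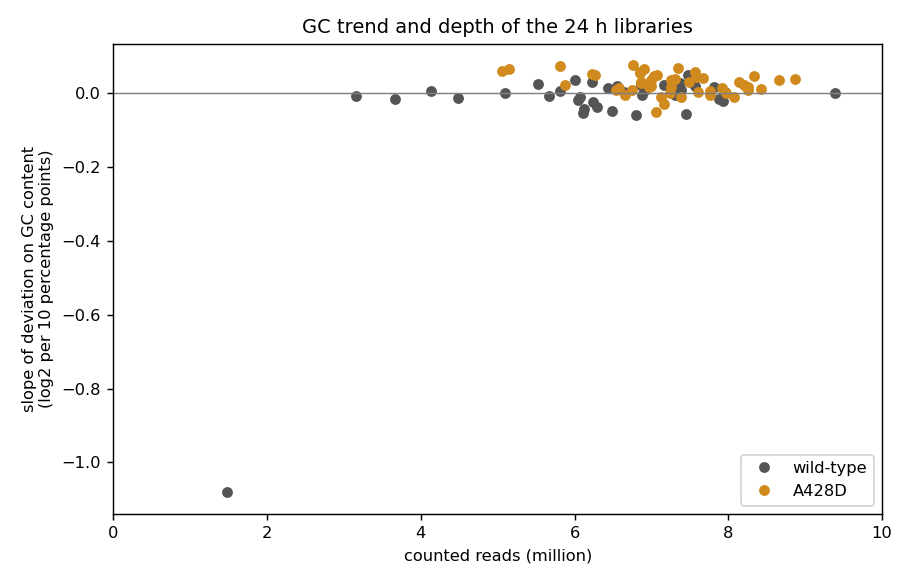
Slope on GC content (log2 per 10 percentage points) of each library's deviation from the mean of all 88 libraries of the 24 h set, against counted reads. The library of wild-type clone 3 given bexobrutideg with venetoclax lies at -1.08 and the 87 others between -0.06 and 0.07.

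Adding pomalidomide to venetoclax raised interferon-stimulated genes in both genotypes. Of 34, 30 rose in each (33 in wild-type and 32 in A428D clones adjusted over the list alone), with IFIT1 at 4.39 ± 0.37 and 4.02 ± 0.30 and MX1 at 2.37 ± 0.21 and 2.40 ± 0.19. The list gave adjusted p = 8.52e-08 in wild-type and 1.85e-08 in A428D clones with an estimated correlation. IKZF1 rose by 0.81 ± 0.07 and 0.74 ± 0.06. IRF4 fell from 600 ± 25.9 to 360 ± 28.3 CPM in wild-type clones (-0.74 ± 0.15) and from 519 ± 77.7 to 337 ± 53 in A428D clones (-0.62 ± 0.14). IRF8 changed by -1.74 ± 0.14 and -1.62 ± 0.12. Plasma cell genes fell for 5 of 20 in wild-type clones by both counts, and 4 fell and 1 rose in A428D clones (5 and 1 adjusted over the list alone). They gave adjusted p = 0.163 and 0.297 with an estimated correlation. Integrated stress response genes fell for 9 of 26 in wild-type clones (11 adjusted over the list alone), with adjusted p = 0.111 with an estimated correlation. In A428D clones 5 of 14 STAT3 and cytokine targets rose (6 adjusted over the list alone), with SOCS1 at 0.73 ± 0.13, and 3 of 14 cereblon substrates rose by both counts. These gave adjusted p = 0.04 and 0.0474 with an estimated correlation (0.0565 for the cereblon list with the clone block). The counts were 1259 in wild-type clones (795 higher, 464 lower, 2572 with the clone block, 2014 with only the groups compared). They were 1183 in A428D clones (688 higher, 495 lower, 2432 with the clone block). In wild-type clones they were 837, 819 and 799 without wild-type clones 2, 4 and 5.

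Compared directly, the BTK degraders differed in IKZF1, LDB3 and LRRN3 in both genotypes. In wild-type clones their differences in IRF4 and MYC did not pass the test. IRF4 differed by -0.18 ± 0.15 (95% interval -0.47 to 0.12) and MYC by -0.29 ± 0.20 (95% interval -0.68 to 0.11). Of the BCR NF-kB targets, 1 of 30 was higher with zelebrudomide (3 adjusted over the list alone, camera adjusted p = 0.0787, and 0.0494 with the clone block). IKZF1 was higher with zelebrudomide by 0.68 ± 0.07 in wild-type and 0.63 ± 0.06 in A428D clones, LDB3 by 1.75 ± 0.21 and 1.52 ± 0.20, and PTP4A3 by 1.44 ± 0.21 and 1.23 ± 0.19. LRRN3 was lower by a log2 change of -1.38 ± 0.24 and -1.50 ± 0.23. In A428D clones 2 of 30 BCR NF-kB targets were higher with zelebrudomide (9 adjusted over the list alone), with CCND2 at 0.79 ± 0.12, and 1 of 14 STAT3 and cytokine targets (4 adjusted over the list alone). Camera gave adjusted p = 0.00581 with an estimated correlation for each. The cereblon list (1 of 14 higher by both counts, IKZF1) gave adjusted p = 0.0455 with an estimated correlation and 0.0767 with the clone block. Interferon-stimulated genes were higher for 2 and 3 of 34 (2, and 7 higher and 1 lower, adjusted over the list alone), with adjusted p = 0.661 and 0.187 with an estimated correlation. The counts were 184 in wild-type clones (127 higher, 57 lower, 663 with the clone block, 425 with only the groups compared, and 92, 91, 104 and 88 without clones 1, 2, 4 and 5). They were 186 in A428D clones (127 higher, 59 lower, 721 with the clone block, 42 with only the groups compared, and 105, 118, 103, 106 and 111 without clones 2 to 6).

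Compared with pomalidomide in wild-type clones, IRF4 was lower with zelebrudomide by a log2 change of -0.85 ± 0.15, MYC by -0.97 ± 0.20, NFKBIA by -1.22 ± 0.10 and IL10 by -3.27 ± 0.36, and IKZF1 by -0.33 ± 0.07 (adjusted p = 0.000409, and 0.101 with no expression filter). BCL2 gave -0.30 ± 0.13 (adjusted p = 0.182, and 0.00824 with the clone block). Lower with zelebrudomide were 21 of 30 BCR NF-kB targets (25 adjusted over the list alone) and 21 of 26 integrated stress response genes (23 adjusted over the list alone). So were 7 of 20 ERK and immediate early genes and 7 of 14 STAT3 and cytokine targets (7 of each adjusted over the list alone). The lists gave adjusted p = 5.52e-11, 1.79e-05, 4.09e-05 and 6.83e-06 with an estimated correlation. Interferon-stimulated genes (14 of 34 lower, 1 higher), MYC and ribosome biogenesis targets (9 of 25 lower), cholesterol synthesis (2 of 18 lower), proliferation (0 of 26) and hypoxia and glycolysis genes (2 of 24 lower) gave adjusted p = 0.121, 0.0715, 0.42, 0.666 and 0.666 with an estimated correlation. In A428D clones 15 of 34 interferon-stimulated genes were lower with zelebrudomide (23 adjusted over the list alone, adjusted p = 1.24e-06 with an estimated correlation), such as IFIT1 (-2.29 ± 0.27), LGALS3BP (-2.09 ± 0.26) and IFI6 (-1.55 ± 0.19). IRF8 was higher by 0.92 ± 0.12, and IKZF1 gave -0.19 ± 0.06 (adjusted p = 0.192, and 0.0193 with the clone block). STAT3 and cytokine targets (0 of 14, 1 lower adjusted over the list alone) and cholesterol synthesis genes (0 of 18 by both counts) gave adjusted p = 0.0482 and 0.747 with an estimated correlation. There were 1112 genes called in wild-type clones (394 higher, 718 lower, 2749 with the clone block, 2415 with only the groups compared, and 667, 735 and 644 without clones 2, 4 and 5). There were 126 in A428D clones (23 higher, 103 lower, 587 with the clone block, 207 with no expression filter, 25 with only the groups compared, and 83, 83 and 80 without clones 2, 4 and 5). Because doses were not given in the sources used here, differences between compounds cannot be read at matched doses.

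Untreated cultures differed from DMSO cultures in most genes (11060 and 10895 of 15354 in wild-type and A428D clones). The CPM values in this paragraph come from these libraries scaled together, and so differ from those of the untreated libraries scaled alone. The AP-1 gene FOS averaged 157 ± 16.2 CPM in untreated and 2.13 ± 0.724 in DMSO wild-type clones. In A428D clones it averaged 507 ± 103 and 3.96 ± 3.07 (7.01 ± 0.28). The glycolytic enzyme ALDOC changed by -6.43 ± 0.22 and -5.90 ± 0.19, and MYC by 1.21 ± 0.13 and 1.03 ± 0.11. BTK changed by -0.44 ± 0.07 and -0.35 ± 0.06, and MCL1 by -0.69 ± 0.08 and -0.26 ± 0.07 (lower in 5 of 5 and 5 of 6 clones). IKZF3 changed by -0.57 ± 0.06 and -0.37 ± 0.05, IKZF1 by 0.15 ± 0.06 and 0.35 ± 0.05, and BCL2 by 0.28 ± 0.08 in A428D clones. The IKZF1 call in wild-type clones (adjusted p = 0.0223) ended without wild-type clones 1, 2 or 4 (0.0607, 0.0527 and 0.085). IRF4 changed by 0.31 ± 0.11 and 0.33 ± 0.10, calls that ended without wild-type clone 1 (0.0678) and A428D clone 3 (0.0542), and the second with only the groups compared as well. Transcripts of cytotoxic lymphocytes differed as well: GNLY averaged 40.6 ± 5.53 and 40.6 ± 3.66 CPM in untreated clones, with 0 counts in the 11 DMSO libraries. A count of 0 there allows up to 0.0388 CPM (3 counts over those libraries, counting error only), which sets a lower bound of about 1050-fold for GNLY. NKG7 averaged 16.3 ± 1.79 and 16.9 ± 0.752 CPM against 0.0318 ± 0.0712 and 0.0758 ± 0.186. Of 9 measured T and NK cell markers 8 were higher in wild-type and 7 in A428D clones by both counts, with adjusted p = 0.0515 and 0.036 with an estimated correlation.

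Among the other lists in untreated against DMSO cultures, 26 and 25 of 26 proliferation genes, 24 and 23 of 25 MYC and ribosome biogenesis targets, and 13 and 15 of 22 ERK and immediate early genes were higher in wild-type and A428D clones, with NOP16 at 1.91 ± 0.10 and 1.48 ± 0.09. Lower were 22 and 22 of 26 B cell identity genes, 22 and 20 of 26 integrated stress response genes, and 17 and 17 of 18 cholesterol synthesis genes. So were 18 and 20 of 24 hypoxia and glycolysis genes and 12 and 11 of 24 BCR and TLR components, with CD72 at -1.95 ± 0.08 and -1.61 ± 0.08. Counts adjusted over the list alone were the same except for 14 ERK genes in wild-type clones. With an estimated correlation the adjusted p lay between 0.0737 and 0.428 for each of these. Plasma cell genes passed in wild-type clones (13 of 20 lower by both counts, adjusted p = 0.392 with an estimated correlation). Epithelial and myeloid markers passed in none of the 26 comparisons run (smallest adjusted p = 0.213 and 0.425). The counts were 11060 of 15354 genes in wild-type clones (5583 higher, 5477 lower) and 10895 in A428D clones (5685 higher, 5210 lower). Untreated and DMSO cultures belong to separately deposited sets of different depth, so that set and exposure cannot be told apart here.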

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

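The tests of T and NK cell transcripts, of STMN2 and TTR and of GC content were chosen after the results had been seen, and those of the T and NK cell transcripts and of STMN2 and TTR were changed after their first result.

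Among 180 tests of a library far from the others of its group, 14 stood apart, where chance gives about 1 in 20. The library of wild-type clone 3 given bexobrutideg with venetoclax accounted for 6 of them: 6.24% of counts from mitochondrial transcripts (others 9.22 to 9.96), and CPM values of 52.8 for BTK (75.3 to 81.1), 21.7 for CRBN (14.5 to 16.5), 746 for IRF4 (214 to 261), 514 for MYC (102 to 138) and 421 for MCL1 (172 to 221). Few reads as the whole cause are argued against by the other 4 libraries thinned to its depth, which correlated with their group at 0.982 or more against 0.744 for this library. A wrong label is argued against too: its correlation with its own group exceeded that with any other by 0.0052, and it lay nearest to its own clone. Loss of GC-rich transcripts is a candidate explanation: its deviation correlated with GC content at -0.73 across 5896 genes, against -0.18 to 0.12 in the other libraries of its group. No biological explanation was tested.

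The wild-type clone 1 library given zelebrudomide with venetoclax stood highest for BTK (86.9 CPM, others 71.1 to 74.9), IKZF1 (293, others 222 to 237) and IKZF3 (176, others 124 to 132). Wild-type clone 2 stood highest in mitochondrial transcripts with zelebrudomide (10.5%, others 8.73 to 8.91) and with pomalidomide (8.98%, others 8.13 to 8.28). CRBN was highest in wild-type clone 5 given pomalidomide with venetoclax (17.8 CPM, others 10.6 to 12.7), and MCL1 in A428D clone 1 under DMSO (251 CPM, others 181 to 204). A428D clone 6 given bexobrutideg with venetoclax held the fewest reads of its group (5.05, others 6.66 to 7.61, in units of 1000000).

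The responses of A428D and wild-type clones differed, by a test of the difference itself, for 155 genes with zelebrudomide and 92 with bexobrutideg. In fits of the groups compared alone, 1 of 50 splits of the clones gave as many genes, the real one (153 and 88, highest other 1 for each). The other splits mix genotypes that already differ under DMSO, so they do not test the response difference by itself.

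The untreated parental library, which enters no comparison, held GNLY at 48.7 CPM, against 0 in the DMSO libraries. GNLY averaged 44.6 CPM over the 12 untreated libraries, NKG7 18.2, CCL5 19.1, GZMA 14.1 and PRF1 7.14, with CD3D at 0.0951 and CD3E at 0.29, and 8 of 14 T and NK cell markers averaged at least 1 CPM, 5 of them above every 24 h library. T or NK cells in the cultures cannot be told apart from other sources by this count, since no value here bounds their share. STMN2 averaged 5.59 CPM and TTR 4.87 CPM in the same libraries. Both were picked because the 24 h libraries nearly lack them, so this test decides nothing about such cells. Reads carried over from other libraries stay open as well: the spread of those 5 markers between untreated libraries lay at a median percentile of 31.8 (0 to 91.1) among genes of like level, which separates neither case. Synthetic spike-in reads split the same way, at 58 to 104 in each untreated library and at most 1 in any 24 h library. Cells in the cultures cannot be the source of those reads, but no value here ties them to the markers. The untreated libraries were deposited as a set of their own, so a batch difference stays open too.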

How the results depend on the processing

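Leaving out the shallowest library was chosen after the data had been seen, and the other alternatives before. Counts of called genes stayed within 1.5 times under DESeq2 and under RLE scaling in 26 of 26 comparisons, with no filter on low counts in 16 of 26, with only the groups compared in 12 of 24, with the clone block in 4 of 26 and without the shallowest library in 20 of 22. No named gene reversed. Named genes lost their call in 2 cases under DESeq2, 2 under RLE, 28 with no filter, 53 with only the groups compared, 18 with the clone block, 1 without the shallowest library and 457 of the removals of single clones, and gained one in 21, 3, 66, 39, 110, 20 and 56.

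With no filter the counts were 1538 for A428D against wild-type clones in DMSO and 1294 untreated, 345 and 288 for the zelebrudomide and bexobrutideg response differences, 660 and 4 for bexobrutideg in wild-type and A428D clones, 2 and 4 for the pomalidomide and venetoclax response differences, 245 for zelebrudomide added to venetoclax in A428D clones and 207 for zelebrudomide against pomalidomide in A428D clones. The cause was not tested.

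With only the groups compared, which leaves fewer libraries to estimate the spread, zelebrudomide gave 2085 in wild-type and 121 in A428D clones, bexobrutideg 1094 in wild-type clones, and pomalidomide 2507 and 845. Added to venetoclax, zelebrudomide gave 92 in A428D clones, bexobrutideg 571 in wild-type clones and pomalidomide 2014 in wild-type clones. Zelebrudomide against bexobrutideg gave 425 and 42, and against pomalidomide 2415 and 25.

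The clone block takes the spread between clones out of the error. In wild-type and A428D clones it gave 2421 and 1007 for zelebrudomide, 1582 and 2 for bexobrutideg, 2879 and 2493 for pomalidomide, and 4595 for venetoclax in A428D clones. Response differences were 1011, 753, 7 and 26 for zelebrudomide, bexobrutideg, pomalidomide and venetoclax. Added to venetoclax, zelebrudomide gave 4863 and 764, bexobrutideg 3798 in wild-type clones and pomalidomide 2572 and 2432. Zelebrudomide against bexobrutideg gave 663 and 721, and against pomalidomide 2749 and 587. Between genotypes, where clone numbers pair nothing, it gave 228 in DMSO and 418 untreated. Some gene lists that did not pass in the fit without a block passed with it, and those are not described. Without the shallowest library the response differences were 276 for zelebrudomide and 140 for bexobrutideg.

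Leaving out each clone in turn gave 437 to 2097 (DMSO) and 412 to 1252 (untreated) between genotypes. Against DMSO, in wild-type and A428D clones, it gave 550 to 1217 and 175 to 376 for zelebrudomide, 161 to 491 and 0 for bexobrutideg (edgeR, where 288 passed an unadjusted p under 0.05 with all clones and DESeq2 called 0), 1001 to 1717 and 957 to 1505 for pomalidomide, and 3705 to 5208 and 1418 to 3169 for venetoclax. The zelebrudomide and bexobrutideg response differences gave 82 to 237 and 48 to 131. Added to venetoclax, zelebrudomide gave 2090 to 3697 and 88 to 213, bexobrutideg 1615 to 2709 in wild-type clones and pomalidomide 799 to 1548 and 893 to 1420. Zelebrudomide against bexobrutideg gave 88 to 241 and 103 to 225, and against pomalidomide 644 to 1364 and 80 to 164.

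The planned removal of libraries under 1000000 reads gave no values, since 0 libraries were that shallow. The wild-type groups given venetoclax with zelebrudomide or bexobrutideg were the shallowest. With 1.5-fold changes planted, 27% of zelebrudomide response differences were recovered.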

Other observations

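The tests in this part were set before their results were seen, except the counts without the shallowest library and the tests of lists for a departure from the sum, which were chosen after the data had been seen.

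Zelebrudomide may keep part of the pomalidomide response in A428D clones. Across the 1183 genes called when pomalidomide was added to venetoclax in A428D clones, a comparison that shares no library with it, the zelebrudomide change correlated with the pomalidomide change at r = 0.84, with a slope of 0.44 and the same sign in 93.4% of genes. The bexobrutideg change gave r = 0.27, a slope of 0.05 and 57.5%.

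The hypothesis that untreated A428D clones carry part of the BTK degrader response of wild-type clones stayed undecided. Across 335 genes called for bexobrutideg in wild-type clones, the untreated difference between genotypes correlated with that response at r = 0.27, between the bounds set for and against it, with the same sign in 63.9% of genes.

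Zelebrudomide with venetoclax departed from the sum of the single log2 changes for 4 genes in wild-type clones (1160 at an unadjusted p under 0.05), among them LBH, CNR1 and TRIP6, named after their values were seen. Without the shallowest library the count was 21, and 804 with the clone block as well. Bexobrutideg with venetoclax gave 4 without that library (13 with it), and 280 with the clone block as well. The bound set beforehand, fewer than 10 genes, was met for zelebrudomide with all libraries and for bexobrutideg without the shallowest one, and not in the other fits named here. It is not taken as evidence against a departure, because the fit without a block leaves the spread between clones in the error and no departure was simulated. Pomalidomide with venetoclax gave 4 in wild-type clones, 13 without the shallowest library, and 628 with the clone block as well. In A428D clones edgeR called 0 for zelebrudomide, bexobrutideg and pomalidomide (311, 243 and 501 at an unadjusted p under 0.05), and 0, 1 and 75 with the clone block and without that library.

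The lists that passed held few called members or none. In wild-type clones with all libraries, BCR NF-kB targets lay below the sum for zelebrudomide (adjusted p = 3.74e-06) and pomalidomide (adjusted p = 4.06e-15), with adjusted p = 0.0214 and 5.22e-05 with an estimated correlation, and adjusted p = 9.09e-05 and 0.0804 for bexobrutideg. Of 30 members 0 were called for zelebrudomide, 0 for pomalidomide and 1 for bexobrutideg. Without the shallowest library bexobrutideg gave 0.0331 for this list with an estimated correlation, with 1 of 30 called. B cell identity genes then lay above the sum (0 of 27 called, adjusted p = 5.23e-05, and adjusted p = 0.037 with an estimated correlation), where they gave 0.95 with all libraries. PI3K-FOXO genes lay above it for zelebrudomide, bexobrutideg and pomalidomide (0 of 17 called in each, adjusted p = 0.0214, 0.00349 and 0.0129 with an estimated correlation). With pomalidomide, interferon-stimulated genes lay above the sum in wild-type and A428D clones (2 and 0 of 34 called, adjusted p = 0.00469 and 0.0054 with an estimated correlation). Integrated stress response genes lay below it in both (0 of 26 called in each, 0.00312 and 0.0115), and STAT3 and cytokine targets in wild-type clones (0 of 14 called, 0.0385, and 0.0815 without the shallowest library). In A428D clones given pomalidomide, mitochondrially encoded transcripts lay above the sum and 3 epithelial markers below it (0 of 13 and 0 of 3 called, adjusted p = 0.0123 for each, and adjusted p = 0.584 and 0.087 with an estimated correlation). Other lists passed at the preset correlation and not with an estimated one.

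Other splits of the libraries were compared with the real one in fits of the groups compared alone, 50 splits being drawn per comparison. Chance is excluded (1 of 50 splits gave as many genes, the real one) for A428D against wild-type clones in DMSO (955, highest other 1) and untreated (859, 0), and for untreated against DMSO cultures in wild-type (11007, 0) and A428D clones (9411, 5). The same held in wild-type clones for zelebrudomide (2085, highest other 1), bexobrutideg (1094, 2), pomalidomide (2507, 0) and venetoclax (6207, 1301). It held there too for zelebrudomide (4238, 0), bexobrutideg (571, 0) and pomalidomide (2014, 1) added to venetoclax, and for zelebrudomide against bexobrutideg (425, 84) and pomalidomide (2415, 1). Splits drawn without regard to clone ignore the pairing of the libraries, so they do not by themselves exclude chance.

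In A428D clones, splits drawn without regard to clone exclude chance (1 of 50) for pomalidomide (845, highest other 220) and venetoclax (2186, 400). They do so for pomalidomide added to venetoclax (894, 177) too. They do not for zelebrudomide added to venetoclax (92, 357) and zelebrudomide against pomalidomide (25, 628), each with 2 of 50. Nor do they for zelebrudomide (121, 403) and zelebrudomide against bexobrutideg (42, 739), each with 3 of 50. Where the fit called 0 genes, 50 of 50 splits give as many whatever the data, and the count decides nothing: bexobrutideg (highest other 620), bexobrutideg added to venetoclax (544) and the pomalidomide and venetoclax response differences (0). Splits with several times the real count point to a structure of the samples, the clones. The clone pairs the libraries, and the splits that part every pair, as the real one does, are the fairer comparison. There are 32 of these in A428D clones, where the highest other count was 0. Against them chance is excluded (1 of 32) for the 8 comparisons within A428D clones that called genes, among them zelebrudomide, zelebrudomide against bexobrutideg and untreated against DMSO. The splits with higher counts therefore keep at least 1 pair together. In wild-type clones these splits number 16, too few for a share under 0.05, and the highest other count was 0.

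The parental library, in no comparison, lay outside the range of untreated wild-type clones for 6 of the 8 genes fixed beforehand. It held MCL1 at 107 CPM (161 to 174 in untreated wild-type clones), MYC at 264 (305 to 326), IKZF1 at 249 (251 to 271), BCL2 at 59.6 (60.8 to 70.9), IKZF3 at 154 (132 to 148) and BTK at 68.3 (55.2 to 63.3). CRBN at 19.5 (17 to 20.4) and IRF4 at 630 (622 to 728) lay inside it.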
